A study of Mus musculus with 12 samples.

How the data were processed

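The series profiled messenger RNA from cortex and hippocampus of mouse embryos at embryonic day 18.5, from control animals and from knockout (KO) animals lacking functional Srrm4. Srrm4, also called nSR100, is a neuronal splicing regulator. Per the labels' protocols, the KO came from a conditional allele bought from the EUCOMM resource, carried by stem cells aggregated with outbred ICR morulae, whose exons 7 and 8 were excised by crossing to mice that carry Cre recombinase under a cytomegalovirus promoter, and the line was kept on a C57Bl/6N background. RNA was purified with Tri Reagent and libraries were made with the Illumina TruSeq kit, per the labels' protocols. The submitters' processing notes name Bowtie, with no version, and the mouse build mm9. The counting rule, the strand setting and the gene annotation are not given in the sources used here.

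Each deposited table holds 1 line per Ensembl gene ID with an RPKM value and a read count made by the authors. The count column was read as whole-number counts of reads per gene, not normalized, as deposited by the authors. The deposited RPKM column is the authors' read count scaled by a length per gene and by the total count of the table. This was checked on 6056 well-counted genes, where the length implied by counts and RPKM differed between tables by factors from 0.998 to 1.0016. The RPKM column of each table also holds 1114 cells with the text "ne", whose meaning is not given in the sources used here. These were treated as missing RPKM values, and the genes concerned held at most 0.00149% of a library's counts. Blank count cells, 4244 to 5054 per table, never stood beside an RPKM above 0 and were read as 0.

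The 12 samples reach 8 tables, because the label of replicate 1 of every group names runs 1 and 2 that share a table. Each table was used as 1 library, which gave 4 groups (cortex control, cortex KO, hippocampus control, hippocampus KO) of 2 libraries each. Total counts ranged from 58210499 to 140052443 per library, and replicate 1 was the deeper library in each group. A floor of 3 counts therefore corresponds to 0.0214 to 0.0515 CPM. The replicates of a group differed by more than counting noise (chi-square per degree of freedom from 31.8 to 64.6), so none was treated as a duplicate. The labels do not say which libraries came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

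The tables hold 22667 gene IDs, of which 20759 were matched to symbols through the gene name table supplied with GENCODE M21; the other 1908 held at most 0.402% of a library's counts and are named by their ID. The build of that annotation (GRCm38) differs from the authors' mm9, so no coordinates are given, and GENCODE M21 was used only for symbols, chromosome names and the order of genes along a chromosome.

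Before the data were examined, the main test was fixed as limma on log2(RPKM + 1), to be replaced by edgeR's quasi-likelihood test should the files hold whole-number counts. They did, so edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, R 4.3.3) on the deposited counts was the main test and limma 3.58.1 became an alternative. Genes passing filterByExpr on the 4 groups (minimum count 10, minimum total count 15) were tested, 16111 in all. The KO effect in cortex, the KO effect in hippocampus, their difference, and the difference between hippocampus and cortex in controls came from a fit of the 4 group means. The KO effect over both tissues and the tissue effect came from an additive model of tissue and genotype, with 4 libraries against 4. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and the standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. All tests were two-sided. Means of RPKM are given ± SD over the 2 libraries of a group.

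For the 33 gene lists, written before the data were examined (706 entries, 696 found in the tables), camera of limma was run on log2 CPM with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and again with an estimated correlation. The lists cover splicing regulators, hosts of neuronal microexons, REST targets, neuronal layers and classes, progenitors, glia, vessels, blood, choroid plexus, neighbouring brain regions, synaptic and channel genes, stress, ribosomal and histone genes and sex-linked genes. The rule for named genes was also fixed then. It takes Srrm4, then, among genes that passed with a mean RPKM of at least 1 in a compared group and no overlap between the libraries compared, the 12 largest log2 fold changes in each direction, and up to 3 passing members of each list by smallest p. Where fewer than 10 genes passed in a genotype contrast, the 10 genes with the smallest p were also taken, as values that did not pass. The 3 members with the highest mean RPKM serve as examples of a list.

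The labels give every group replicates 1 and 2. Same-numbered libraries deviated together from their group means, with correlations across genes of 0.267 (cortex control and cortex KO), 0.368 (cortex control and hippocampus control), 0.282 (cortex KO and hippocampus control), 0.0961 (cortex control and hippocampus KO), 0.380 (cortex KO and hippocampus KO) and 0.107 (hippocampus control and hippocampus KO). The number also coincides with sequencing in 2 runs or in 1 run, per the labels. The fit with the replicate number as a block was therefore treated as a batch correction, and its value is printed beside a result where it moves a count by more than 1.5 times.

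The scripts were tested on simulated counts drawn from the real means, library sizes and dispersions of the 16111 genes, with 200 genes changed by known folds, 50 of each size. For the KO effect in cortex, edgeR recovered 44.0% of genes changed 1.5-fold, 82.0% of those changed 2-fold and 92.0% of those changed 4-fold, with 10 false calls. For the KO effect in hippocampus it recovered 32.0%, 80.0% and 90.0%, with 8 false calls, and for the KO effect over both tissues 70.0%, 86.0% and 98.0%, with 8 false calls. For the interaction it recovered 12.0%, 56.0% and 86.0%, with 10 false calls. For the tissue effect it recovered 84.0%, 94.0% and 96.0%, with 15 false calls, and for the tissue effect in controls 48.0%, 78.0% and 86.0%, with 14 false calls. DESeq2 made 43, 32 and 23 false calls for the KO effect in cortex, in hippocampus and over both tissues. None of 32 random gene lists was called by camera in each of 3 simulations, and the list of raised genes was called in each. Simulated genes varied independently, so these runs cannot show how camera treats lists whose members vary together. Ribosomal protein genes, for example, had an estimated correlation of 0.502 over both tissues. The simulated libraries also carried no effect of the replicate number, so the recovered shares may not hold for the real libraries.

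The alternatives were limma on log2(RPKM + a pseudocount of 0.1, 1 or 5), no filter on low counts, RPKM of at least 1 or 5 in at least 2 libraries, median-ratio scaling, quantile-normalized RPKM, robust dispersion, DESeq2 1.42.0, the replicate block, each library left out in turn, single-tissue fits, and models that treat cortex and hippocampus libraries of a genotype and number as a pair. Chosen after seeing the data were a covariate for the level of Y-linked genes, a fixed pair term for the tissue effect, camera on the interaction, camera without hippocampus KO replicate 1, and correlations of fold changes within each replicate number. Alternative splicing, the usual readout for this regulator, was not analysed here, because gene totals carry no exon-level values.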

Results

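The data comprised gene counts and RPKM values from cortex and hippocampus of mouse embryos, control or Srrm4 KO, with 2 libraries in each of the 4 groups. Total counts were 132754979 and 68213778 in cortex control, 140052443 and 62778943 in cortex KO, 121366651 and 68649479 in hippocampus control and 122744872 and 58210499 in hippocampus KO (replicates 1 and 2). Tissue set most of the variation, since the first principal component carried 79.1% of the variance and separated the 4 hippocampus from the 4 cortex libraries. Mitochondrial genes took 4.40% of counts in hippocampus KO replicate 1 and 3.14% to 3.44% in the other 7 libraries. Ribosomal protein genes took 1.56% there and 1.22% to 1.29% elsewhere.

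The targeted gene was examined before all others. Srrm4 (ENSMUSG00000063919) lay at 24.7 ± 0.71 RPKM in cortex control and 7.545 ± 0.81 RPKM in cortex KO (mean ± SD, n = 2 each). In hippocampus it lay at 26.9 ± 1.29 RPKM in controls and 5.92 ± 0.34 RPKM in KO. The log2 fold change was -1.71 (SE 0.10, adjusted p = 0.00088, edgeR) in cortex and -2.22 (SE 0.10, adjusted p = 0.00025, edgeR) in hippocampus. Over both tissues Srrm4 fell by 1.96 on the log2 scale (SE 0.11, adjusted p = 0.00016, edgeR), with all 4 KO libraries below all 4 controls, which matches the genotype labels. Counts in the KO libraries remained between 2664 and 8448, and a gene total does not separate reads of the excised exons 7 and 8 from reads of the other exons.

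**Figure D1:**
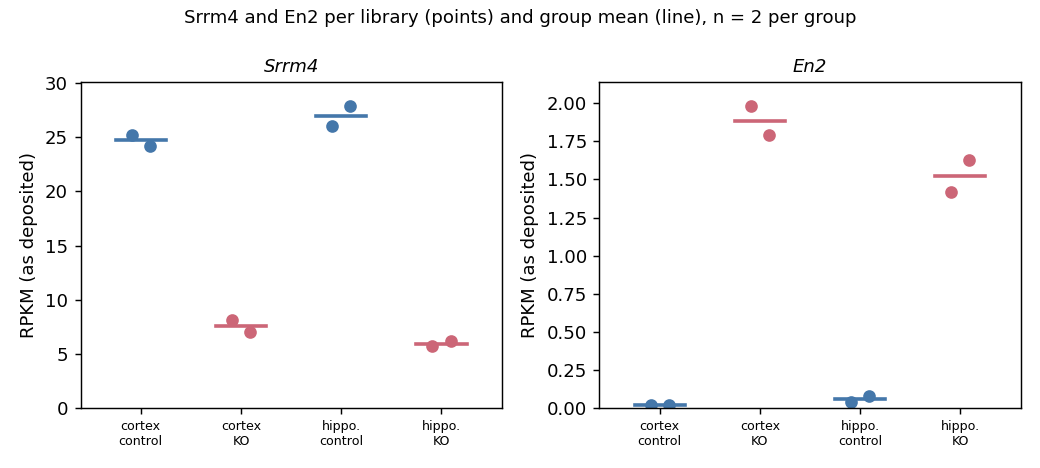
RPKM of Srrm4 and En2 (vertical axes, as deposited) in the 4 groups (horizontal axes), with a point per library and a line at the group mean (n = 2). Srrm4 lies between 24.22 and 27.86 in controls and between 5.68 and 8.12 in KO libraries, and En2 between 0.02 and 0.08 in controls and between 1.42 and 1.98 in KO libraries.

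The first genotype comparison asked which genes changed in KO cortex. En2, a homeobox gene known for its role in midbrain and hindbrain development, rose from 0.02 RPKM in both control libraries to 1.885 ± 0.13 RPKM in KO (log2 fold change 6.44, SE 0.30, adjusted p = 0.00028, edgeR), on 10 and 5 counts in controls against 964 and 391 in KO. Hddc3, which encodes a small HD-domain hydrolase, rose from 8.105 ± 0.70 to 19.995 ± 2.06 RPKM (log2 fold change 1.31, SE 0.12, adjusted p = 0.017, edgeR). With Srrm4 these were the 3 genes of 16111 that passed, 2 higher and 1 lower. The En2 counts may be reads of the engineered Srrm4 allele, a candidate weighed below. Among the genes with the smallest p that did not pass were Micu2, a regulator of mitochondrial calcium uptake, with a log2 fold change of 0.58 (SE 0.07), Antxr1, an anthrax toxin receptor, with 0.66 (SE 0.09), Gemin8, a member of the SMN complex, with 1.53 (SE 0.21), and Napb, which encodes beta-SNAP of the SNARE recycling machinery, with -0.52 (SE 0.07). Their adjusted p ran from 0.16 for Micu2 to 0.23 for Napb (edgeR). Genes at an unadjusted p under 0.05 numbered 183, against 805.55 expected by chance alone. So large a shortfall points to p-values that ran high in this fit. Few calls therefore do not show that few genes changed. For this contrast the simulation gave 43 false calls with DESeq2 against 10 with edgeR. A larger count with DESeq2 therefore does not by itself show more changed genes. DESeq2 called 11 genes, and Hddc3 missed the threshold without cortex control replicate 1 (adjusted p = 0.334), cortex control replicate 2 (0.158), cortex KO replicate 2 (0.137), hippocampus KO replicate 1 (0.0685) or hippocampus KO replicate 2 (0.0661, edgeR), and from the 4 cortex libraries alone (0.174).

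In KO hippocampus, En2 rose from 0.06 ± 0.03 to 1.525 ± 0.15 RPKM (log2 fold change 4.85, SE 0.26, adjusted p = 0.00053, edgeR) and Hddc3 from 10.3 ± 1.07 to 22.3 ± 1.44 RPKM (log2 fold change 1.09, SE 0.12, adjusted p = 0.048, edgeR). Napb fell from 25.4 ± 0.36 to 15.7 ± 0.35 RPKM (log2 fold change -0.72, SE 0.08, adjusted p = 0.048, edgeR). These genes and Srrm4 were the 4 that passed, 2 higher and 2 lower, and 614 genes had an unadjusted p under 0.05. Gemin8 (log2 fold change 1.54, SE 0.20, adjusted p = 0.20), Duxbl3 (1.74, SE 0.25, adjusted p = 0.25) and Micu2 (0.45, SE 0.07, adjusted p = 0.50, edgeR) did not pass. Duxbl3, like Tmem254c, belongs to a family of near-identical copies whose reads the counting could split, so its value is uncertain. Hddc3 and Napb both missed the threshold whichever of the 8 libraries was left out (adjusted p from 0.0762 to 0.715 and from 0.108 to 0.727, edgeR), which left 2 genes in 7 of these fits and 7 genes without hippocampus control replicate 1, and 2 genes passed from the 4 hippocampus libraries alone. DESeq2 called 18 genes, limma on log2(RPKM + 0.1) 7, and edgeR on genes with at least 1 or 5 RPKM in at least 2 libraries 2 and 1. For this contrast the simulation gave 32 false calls with DESeq2 against 8 with edgeR.

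The KO effect over both tissues was fitted with 4 KO against 4 control libraries counted as independent. Replicate 2 libraries of a genotype had similar levels of Y-linked genes in cortex and hippocampus, so both tissues may come from the same embryos. Different embryos of the same sex would match as well, so this does not show it. In replicate 1 the summed Y-linked CPM in cortex and hippocampus were 35.3 and 39.6 in control but 25.4 and 49.8 in KO. With the mean of both tissues as the unit, 4 genes passed (limma). With the libraries counted as independent, 10 genes passed, 6 higher and 4 lower. Besides En2 (log2 fold change 5.54, SE 0.28) and Hddc3 (1.20, SE 0.08), the genes that rose were Gemin8 (1.54, SE 0.14), Antxr1 (0.58, SE 0.06), Proser3 (0.54, SE 0.07) and Micu2 (0.51, SE 0.05), with adjusted p from 0.00014 for En2 to 0.032 for Proser3 (edgeR). Besides Srrm4, Napb fell (-0.62, SE 0.06, adjusted p = 0.0057), as did Nlrp5-ps, a pseudogene (-1.17, SE 0.13, adjusted p = 0.011), and Cldn34c1, a claudin family member (adjusted p = 0.0046, edgeR). Cldn34c1 had 306 counts in cortex controls and 1 in cortex KO, and 246 counts in hippocampus controls and 2 in hippocampus KO. Its KO to control ratio, from pooled CPM, was 0.0055, with a 95% exact interval from 0.0011 to 0.0163 that covers counting error only. Its sibling genes and those of Nlrp5-ps are similar in sequence, so both values are uncertain where reads could be split between copies. Each of these 10 genes had both KO libraries beyond both controls in each tissue.

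**Figure D2:**
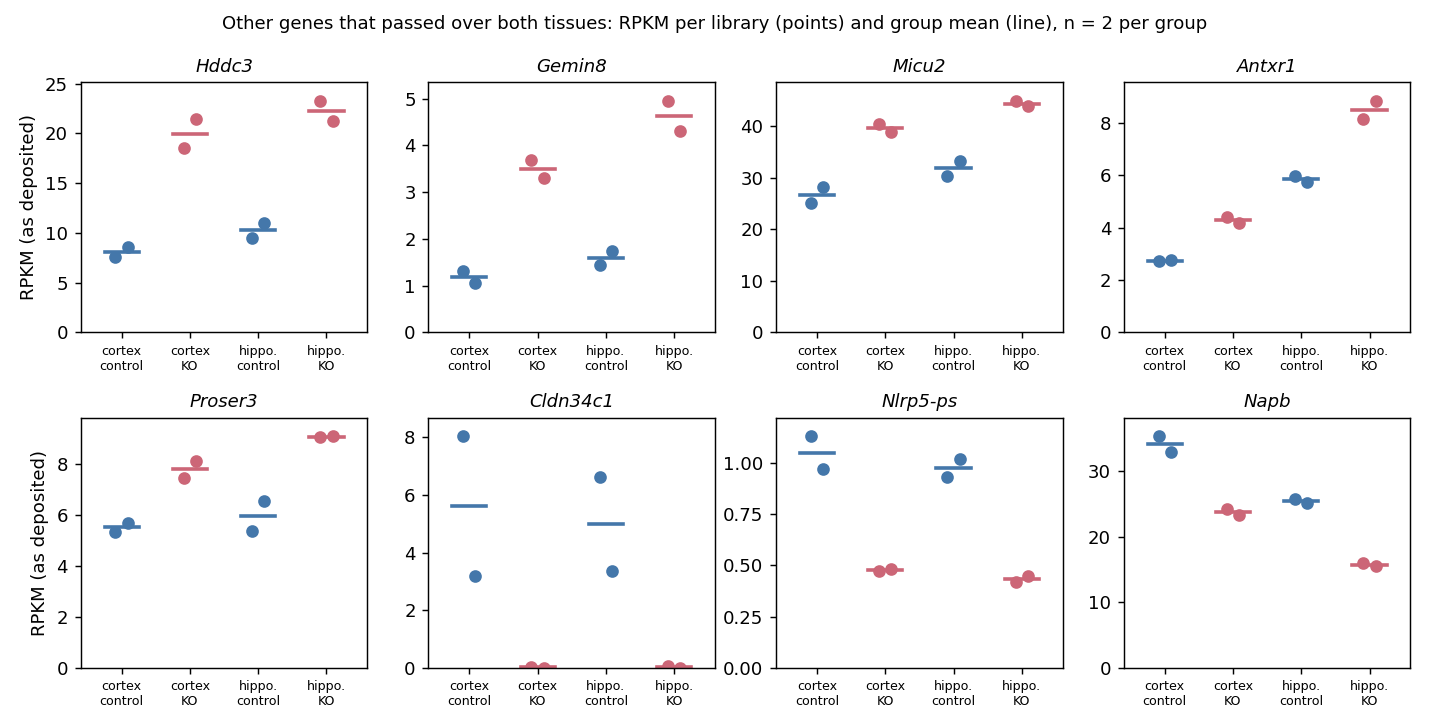
RPKM as deposited (vertical axes) of the 8 genes besides Srrm4 and En2 that passed over both tissues, in the 4 groups (horizontal axes), with a point per library and a line at the group mean (n = 2). Hddc3 lies between 18.54 and 23.28 in KO libraries and between 7.61 and 11.03 in controls, and Cldn34c1 at 0.07 or below in KO libraries and at 3.2 or above in controls.

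Genes at an unadjusted p under 0.05 over both tissues numbered 713, against 805.55 expected by chance. The replicate number, which coincides with sequencing in 2 runs or in 1, moved the count: with it as a block, 22 genes passed (14 higher, 8 lower), including the 10. DESeq2 called 37 genes, but it made 23 false calls in the simulation of this contrast against 8 with edgeR. Limma on the mean of both tissues per genotype and number called 4. With these means Gemin8 (adjusted p = 0.287), Antxr1 (0.356), Proser3 (1.00), Micu2 (0.440), Nlrp5-ps (0.843) and Napb (0.249) did not pass. With the pairs as a random block (duplicateCorrelation) Antxr1 (0.112), Proser3 (0.110) and Nlrp5-ps (0.112, limma) did not. The count was 5 without cortex control replicate 1 or cortex KO replicate 2, and 6 without hippocampus control replicate 2 or hippocampus KO replicate 1. Srrm4, En2, Gemin8 and Hddc3 passed with each library left out and Proser3 with none (adjusted p from 0.0731 to 0.172). Nlrp5-ps passed only without cortex control replicate 2 (0.0527 to 0.125 in the other 7 fits). Antxr1 missed the threshold without replicate 1 or 2 of cortex control (0.125, 0.0795), replicate 2 of cortex KO (0.0625), of hippocampus control (0.0764) or of hippocampus KO (0.0690). Napb missed it without cortex control replicate 1 (0.0834), cortex KO replicate 2 (0.0503), hippocampus control replicate 2 (0.0518) or hippocampus KO replicate 1 (0.0591). Micu2 missed it without cortex control replicate 1 (0.0543) or cortex KO replicate 2 (0.0503), and Cldn34c1 without hippocampus KO replicate 1 (0.0633, edgeR).

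The fixed gene lists were compared for shifts shared by their members over both tissues. Of the 33 lists, 11 passed, 5 upward and 6 downward, while only Napb of the 683 tested members passed alone over all genes tested. All 37 ribosomal protein genes had positive log2 fold changes (median 0.11, adjusted p = 3.7e-11, camera), among them Rpl32 at 0.09 (SE 0.08) and Rps9 at 0.09 (SE 0.05). Hippocampus KO replicate 1 stood apart in this list, with a mean level of 0.19 on a log2 scale centred per gene against 0.04 or lower in the other 7 libraries, and it also had the highest mitochondrial share (4.40%). Positive log2 fold changes were also found for all 17 microglia genes (median 0.14, adjusted p = 8.6e-10, camera), such as the complement genes C1qb at 0.25 (SE 0.08) and C1qc at 0.27 (SE 0.08). Of 10 erythroid genes 8 were positive (median 0.54, adjusted p = 5.8e-05, camera), with the globins Hbb-bs at 0.58 (SE 0.14) and Hba-a2 at 0.61 (SE 0.24); adjusted over the list alone, 6 were higher and 1 lower. Intermediate progenitor genes (median 0.09, or 0.04 on quantile-normalized values, 11 of 14 positive, adjusted p = 0.00036, camera) also shifted upward. So did Cajal-Retzius genes (median 0.11, 9 of 10 positive, adjusted p = 0.0013, camera). Adjusted over the list alone, 2 intermediate progenitor genes and 1 microglia gene were higher. With an estimated correlation none of these held (adjusted p = 0.42 for microglia and erythroid genes and 0.64 for ribosomal protein, intermediate progenitor and Cajal-Retzius genes).

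The lists that shifted downward over both tissues held neuronal genes and the sex-linked genes. Synaptic vesicle release genes had a median of -0.11 with 4 of 28 positive (adjusted p = 5.8e-05, camera), among them Vamp2 at -0.10 (SE 0.09) and Rab3a at -0.11 (SE 0.08). Glutamate and GABA receptor genes had a median of -0.11 with 6 of 28 positive and REST-repressed neuronal genes, targets of a repressor of neuronal genes, -0.08 with 6 of 33 positive (adjusted p = 0.0013 for both, camera). Neurite outgrowth and cytoskeleton genes had -0.08 with 2 of 28 positive (adjusted p = 0.0036) and GABAergic interneuron genes -0.11 with 4 of 20 positive (adjusted p = 0.019, camera). In KO cortex none of these 5 neuronal lists passed: the medians were -0.03 for synaptic vesicle release and receptor genes, -0.02 for REST-repressed genes, -0.01 for neurite genes and 0.07 for interneuron genes (adjusted p from 0.063 to 0.62, camera). Hippocampus KO replicate 1, with the highest mitochondrial share (4.40%), had the lowest mean level of the synaptic vesicle (-0.32), REST-repressed (-0.36) and neurite lists (-0.39) on the scale centred per gene. Its level of the interneuron list was the lowest too (-0.66), with hippocampus KO replicate 2 at -0.54. The 4 Y-linked genes tested, Ddx3y, Kdm5d, Uty and Eif2s3y, had a median of -2.18 (adjusted p = 0.00082, camera). With an estimated correlation the adjusted p was 0.64 for the synaptic, receptor, REST-repressed and sex-linked lists, 0.80 for the cytoskeletal list and 0.91 for the interneuron list. The levels of Y-linked genes moved with genotype in replicate 2: their summed CPM were 144 and 148 in cortex and hippocampus control replicate 2, 0.319 and 0.412 in KO replicate 2, and between 25.4 and 49.8 in the 4 replicate 1 libraries. In replicate 2 the KO effect may therefore be mixed with a difference in embryo sex.

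The lists closest to the known role of Srrm4 in splicing did not pass. Of the 50 tested hosts of neuronal microexons and the 29 tested splicing regulators none passed in cortex, hippocampus or both tissues, over all genes or adjusted over the list alone. Over both tissues the microexon hosts Ptprs, L1cam and Apbb1 had log2 fold changes of 0.12 (SE 0.06), -0.02 (SE 0.09) and -0.05 (SE 0.07), and the splicing regulators Elavl3, Khdrbs3 and Celf2 -0.05 (SE 0.09), -0.03 (SE 0.05) and -0.01 (SE 0.05).

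Within KO cortex 6 lists passed, and with the replicate block also the Cajal-Retzius list (adjusted p = 0.037 against 0.14 without it, camera). Microglia genes shifted upward (median 0.20, or 0.13 on log2(RPKM + 1), 15 of 17 positive, adjusted p = 4.1e-09, camera). Erythroid (0.43, adjusted p = 0.00071), ribosomal protein (0.06, adjusted p = 0.0019), intermediate progenitor (0.10, adjusted p = 0.0045) and striatal and ventral forebrain genes (0.10, adjusted p = 0.015) also shifted upward, and sex-linked genes downward (-2.57, adjusted p = 0.0019, camera). Once the correlation was estimated, the adjusted p (camera with an estimated correlation) was 0.77 for microglia and erythroid genes and 0.84 for the other 4 lists. No member passed over all genes, and adjusted over the list alone 2 erythroid genes were higher and 1 synaptic vesicle release gene lower.

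Within KO hippocampus 13 lists passed. GABAergic interneuron genes shifted downward, with 17 of 20 negative (median -0.29, adjusted p = 2.1e-08, camera). None passed over all genes and 10 were lower adjusted over the list alone. Sst, the somatostatin gene, went from 40.7 ± 0.82 to 29.0 ± 3.10 RPKM (log2 fold change -0.52, SE 0.09, adjusted p = 0.58, edgeR), while Npy (-0.01, SE 0.12) and Calb2 (0.00, SE 0.12) did not pass either. Synaptic vesicle release (-0.21), REST-repressed (-0.16), receptor (-0.16), neurite (-0.15), oligodendrocyte lineage (-0.17), sex-linked (-1.83) and choroid plexus lists (-0.45) also shifted downward in their medians, with adjusted p from 1.3e-05 to 0.034 (camera). With the replicate block the sex-linked list did not pass (adjusted p = 0.077, camera). Oligodendrocyte genes included Olig1 at -0.38 (SE 0.13) and Olig2 at -0.37 (SE 0.09). Ribosomal protein (0.16, 37 of 37 positive), microglia (0.19), erythroid (0.62), Cajal-Retzius (0.15) and intermediate progenitor genes (0.08, or 0.05 on quantile-normalized values) shifted upward, with adjusted p from 3.3e-10 to 0.0090 (camera). The adjusted p with an estimated correlation was 0.69 for the sex-linked and choroid plexus lists and 0.58 for the other 11. Over all genes only Napb passed among list members, and adjusted over the list alone 1 synaptic vesicle release gene was lower and 1 intermediate progenitor gene higher. The choroid plexus median changed sign with the scaling, to 0.05 on log2(RPKM + 1) and 0.02 on quantile-normalized values, and its marker Ttr lay at 82.9 ± 98.3 RPKM in controls and 25.5 ± 1.94 in KO. Without hippocampus KO replicate 1, the library with the highest mitochondrial share, the interneuron list stayed lower (median -0.22). The set of lists that passed camera then changed in both directions, with a single KO hippocampus library left. The ribosomal protein, synaptic vesicle, neurite and REST-repressed lists no longer passed. The cell cycle and pericyte lists newly passed downward, and the hypoxia, immediate early and voltage-gated channel lists upward.

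**Figure D3:**
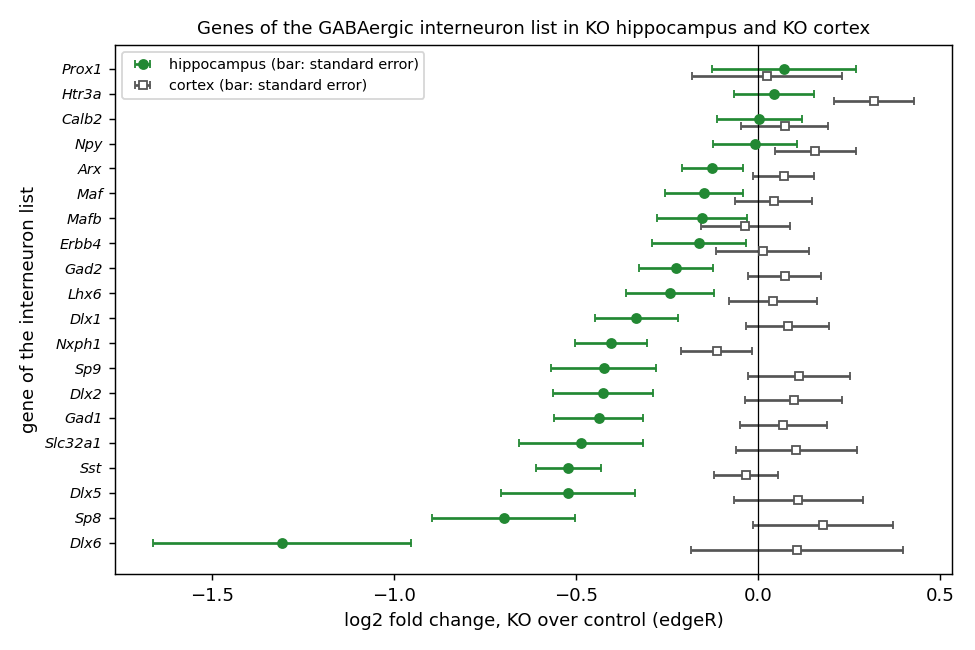
Log2 fold change of KO over control (horizontal axis, edgeR, bars for the standard error) of the 20 tested genes of the interneuron list (vertical axis) in hippocampus (filled circles) and cortex (open squares), 2 libraries per group. In hippocampus 17 of the 20 genes are negative with a median of -0.29, and in cortex the median is 0.07.

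The genotype by tissue interaction asked whether the KO effect differed between hippocampus and cortex. No gene passed in edgeR, and DESeq2 called 0 genes. An unadjusted p under 0.05 was reached by 158 genes in edgeR, against 805.55 expected by chance. These p-values too ran high, so the missing calls do not show equal KO effects in the tissues. Srrm4 itself differed by -0.51 (SE 0.14, adjusted p = 1.00, edgeR), and the small p values included Sst at -0.49 (SE 0.13), Ngef at -0.49 (SE 0.12) and Htr1b, a serotonin receptor gene, at -1.50 (SE 0.42), all at adjusted p = 1.00 (edgeR).

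The log2 fold changes of the KO in cortex and in hippocampus were correlated across the 16111 genes with Pearson's r of 0.362 and Spearman's rho of 0.172. Genes are not independent replicates, and no test was made. The tissues share no control libraries, but r depended on which replicates were set against each other: it was 0.261 between the replicate 1 differences and 0.329 between the replicate 2 differences of both tissues, and 0.0672 and 0.0964 with the numbers crossed. Among 10183 genes with at least 5 RPKM in at least 2 libraries r was 0.622 and rho 0.210. A few genes with large changes in both tissues may weigh heavily on r. In cortex and hippocampus En2 had log2 fold changes of 6.44 and 4.85, Cldn34c1 -7.81 and -6.67, and Srrm4 -1.71 and -2.22. The Y-linked genes had medians of -2.57 and -1.83. Leaving these genes out was not tried, so r does not show a broadly shared KO effect.

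The regional comparison, which also checks the tissue labels, gave 8712 genes that differed between hippocampus and cortex, 4679 higher in hippocampus and 4033 lower (edgeR, 4 libraries each). The excess of genes higher in hippocampus depended on the scaling: the split was 4661 higher and 2580 lower on log2(RPKM + 1) with limma, 3479 and 3382 on quantile-normalized values, 4392 and 4380 with median-ratio scaling and 4365 and 4470 with DESeq2. Hippocampus was marked by Wnt3a (log2 fold change 7.52, SE 0.28) and Wnt8b (7.33, SE 0.34), signals of the medial edge of the developing cortex, by Lmx1a (5.56, SE 0.19), a homeobox gene, and by Pdlim3 (5.84, SE 0.13), Cnmd (5.04, SE 0.15) and Cyp1b1 (4.96, SE 0.19). Wnt8b lay at 7.47 RPKM in hippocampus controls and 0.045 RPKM in cortex controls. Cortex libraries held more of the transcription factors Fezf1 (-6.21, SE 0.32), Tfap2d (-5.66, SE 0.24) and Foxp2 (-4.38, SE 0.21). They also held more Tac1 (-5.37, SE 0.14), Isl1 (-4.81, SE 0.52) and Drd2 (-4.12, SE 0.13), genes known from striatal neurons. The adjusted p of all these genes was 4.8e-05 or smaller (edgeR). Srrm4 did not differ (-0.20, SE 0.11, adjusted p = 0.14, edgeR).

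Several predicted genes with repeated copies also stood out. Gm10800 lay at 0.46 ± 0.08 RPKM in cortex controls and 35.6 ± 26.4 RPKM in hippocampus controls (log2 fold change 6.78, SE 0.58, adjusted p = 1.2e-05, edgeR). Gm10720 had 0 counts in all 4 cortex libraries and 143 in the hippocampus libraries, at least 51.9-fold higher against a floor of 3 counts over the cortex libraries together. Reads of these genes can fall on near-identical copies, so the values are uncertain.

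Of the 33 lists 22 passed between the tissues, 10 higher and 12 lower in hippocampus, with adjusted p from 5.1e-14 to 0.037 (camera), and 505 of the 683 tested members passed alone. With an estimated correlation none of the 22 lists passed, the adjusted p running from 0.14 for the striatal list to 0.49 for astrocytes. The hippocampal markers had 15 of 20 genes higher and 3 lower (median 1.70), among them Neurod1 (2.83, SE 0.08), Lhx9 (3.45, SE 0.09) and Zbtb20 (2.62, SE 0.10). All 10 Cajal-Retzius genes were higher (median 1.92), with Nhlh2 at 2.83 (SE 0.06) and Trp73 at 2.18 (SE 0.06). All 30 cell cycle genes were higher (median 0.75), with Mcm3 at 0.93 (SE 0.06), as were 12 of 14 intermediate progenitor genes (median 1.06), with Eomes at 1.53 (SE 0.05) and Mfap4 at 3.34 (SE 0.06), and 13 of 18 radial glia genes (median 0.69), with Hopx at 2.85 (SE 0.08) and Vim at 1.71 (SE 0.06). Astrocyte genes (11 of 15 higher, median 0.71), with Gfap at 3.31 (SE 0.09), microglia genes (16 of 17 higher, median 0.78), choroid plexus genes (14 of 19 higher, median 1.5005), pericyte and meningeal genes (12 of 20 higher, median 0.40) and endothelial genes (10 of 18 higher, median 0.27) completed the lists that were higher in hippocampus.

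The lists lower in hippocampus were led by the striatal and ventral forebrain markers, of which all 18 were lower (median -3.13, adjusted p = 5.1e-14, camera), with Ppp1r1b at -2.84 (SE 0.09), Rarb at -3.64 (SE 0.08) and Drd1 at -2.91 (SE 0.07). In cortex controls Isl1 lay at 10.25 and 12.95 RPKM and Ppp1r1b at 30.63 and 30.37 RPKM. The cortex libraries may therefore hold ventral forebrain tissue. Whether this adds to the lower interneuron and other neuronal lists in hippocampus was not tested. GABAergic interneuron genes had 17 of 20 lower (median -1.01), with Sst at -2.42 (SE 0.10) and Npy at -2.53 (SE 0.08), while Calb2 was higher (2.11, SE 0.08). Upper-layer genes had 10 of 12 lower (median -0.96), with Cux2 at -1.39 (SE 0.06) and Rorb at -2.38 (SE 0.11), and deep-layer and subplate genes 10 of 17 lower (median -1.14), with Tbr1 at -1.28 (SE 0.04) and, in the other direction, Crym at 2.49 (SE 0.10). Oligodendrocyte lineage genes had 11 of 15 lower (median -0.51), neurite and cytoskeleton genes 22 of 28 (-0.44), REST-repressed genes 25 of 33 (-0.36), synaptic vesicle genes 19 of 28 (-0.36), receptor genes 15 of 28 (-0.33), splicing regulators 17 of 29 (-0.25), voltage-gated channels 15 of 26 (-0.23) and microexon hosts 28 of 50 (-0.21). The splicing repressor Ptbp1 was higher in hippocampus (0.69, SE 0.05) and Elavl4 lower (-0.50, SE 0.05). Adjusted over the list alone, 18 striatal genes were lower and 10 Cajal-Retzius and 30 cell cycle genes higher. The deep-layer list missed the threshold with the replicate block (adjusted p = 0.059) and with median-ratio scaling (0.051, camera), and its median was -0.56 on log2(RPKM + 1) and -0.66 on quantile-normalized values. Other medians that moved by more than 1.5 times kept their direction: channels (-0.13) and microexon hosts (-0.12) on log2(RPKM + 1), and endothelial (0.12), microglia (0.49), pericyte (0.23) and choroid plexus genes (0.97) on quantile-normalized values. The other 11 lists did not pass: REST complex, axon guidance, thalamic, erythroid, immediate early, hypoxia, stress response, apoptosis, ribosomal protein, histone and sex-linked genes.

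**Figure D4:**
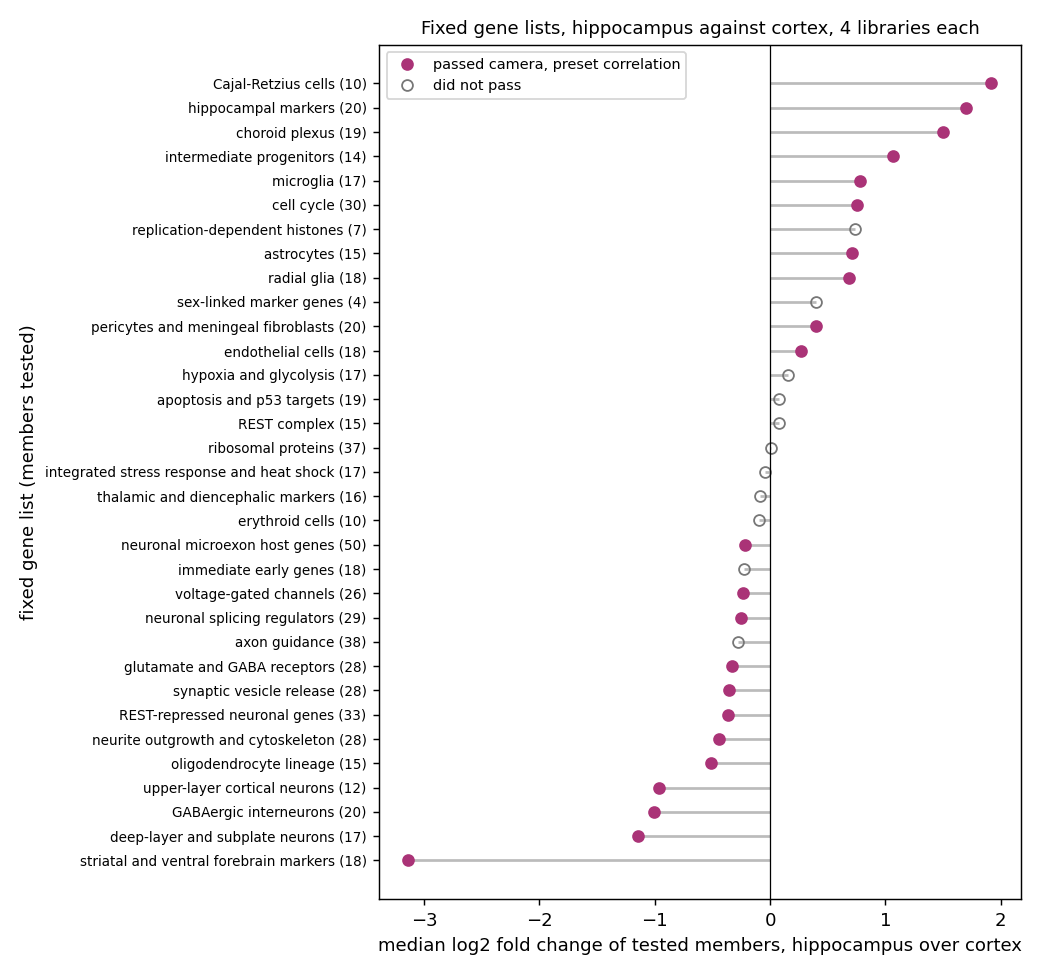
Median log2 fold change of the tested members of each fixed list, hippocampus over cortex (horizontal axis, 4 libraries each), with lists on the vertical axis and filled points for lists that passed camera with the preset correlation. The striatal list lies lowest at -3.13 and the Cajal-Retzius list highest at 1.92.

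In controls alone, 2 libraries against 2, 5464 genes differed between the tissues, 3066 higher in hippocampus and 2398 lower (edgeR). Wnt8b (log2 fold change 7.47, SE 0.53), Wnt3a (6.90, SE 0.34) and Pdlim3 (5.99, SE 0.19) again lay among the largest increases and Fezf1 (-7.32, SE 0.43) and Tfap2d (-6.23, SE 0.31) among the largest decreases. The count was 3189 without cortex control replicate 1 and 3040 among genes with at least 5 RPKM in at least 2 libraries, and on log2(RPKM + 1) with limma 2926 genes were higher and 1540 lower.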

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

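The tests of the En2 to Srrm4 ratio, of the Y-linked level, of the ventral forebrain markers, of single hippocampus libraries and of lists in the interaction were chosen only after the result was seen.

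The KO effect on 11 gene lists differed between cortex and hippocampus by camera on the interaction, as a median over the list (cortex, then hippocampus). GABAergic interneuron genes went from 0.07 to -0.29 (adjusted p = 5.8e-12), ribosomal protein genes from 0.06 to 0.16 (0.0028) and oligodendrocyte lineage genes from 0.02 to -0.17 (0.0060). At an adjusted p of 0.0062 each, striatal and ventral forebrain genes went from 0.10 to -0.16 (in hippocampus -0.07 on log2(RPKM + 1), -0.05 on quantile-normalized values and -0.02 without hippocampus KO replicate 1), synaptic vesicle release genes from -0.03 to -0.21, REST-repressed genes from -0.02 to -0.16, and neurite and cytoskeleton genes from -0.01 to -0.15. Choroid plexus genes went from 0.20 to -0.45 (0.0090), with a hippocampal median that changed sign on RPKM values, receptor genes from -0.03 to -0.16 (0.017), axon guidance genes from 0.05 to -0.06 (0.019) and pericyte and meningeal genes from 0.06 to -0.10 (0.0498). On log2(RPKM + 1) several of these medians were smaller: in cortex 0.01 for pericyte, 0.03 for choroid plexus and 0.0059 for oligodendrocyte genes, and in hippocampus -0.04 for pericyte, -0.03 for axon guidance and -0.11 for oligodendrocyte genes. Without hippocampus KO replicate 1, which had the highest mitochondrial share (4.40%), the KO hippocampus shift itself did not pass for ribosomal protein (0.052), synaptic vesicle (0.054), neurite (0.144) and REST-repressed genes (0.149), and the difference between tissues was not tested without it. With an estimated correlation none passed (adjusted p = 0.57 for interneurons and 0.82 for the other 10), and no single gene passed the interaction in edgeR (158 at an unadjusted p under 0.05; 0 in DESeq2).

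En2 was counted in all 4 KO libraries and hardly in the controls. Midbrain or hindbrain cells are argued against by their own markers: 17 tested markers low in controls had a median log2 fold change of 0.10 (0.1002, quartiles -0.21 and 0.22, 0 passing; edgeR), against 5.54 for En2, and En1 lay at 0.03 RPKM in controls and 0.035 in KO. The ratio of En2 to Srrm4 RPKM varied by 3.521% (CV) over the 4 KO libraries, and none of 2406 genes matched on mean count had a CV to Srrm4 as low (median 33.7%). A candidate explanation is therefore a stretch of En2 carried by the engineered Srrm4 allele and read through with it, which these gene totals cannot show directly. An effect of losing Srrm4 on En2 itself was not tested and stays open, and the higher counts alone do not show one.

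The 8 other genes that passed over both tissues may reflect the loss of Srrm4, but strain differences and sex were weighed against it. Different shares of male and female embryos are argued against as the whole cause: with the Y-linked level as a covariate the log2 fold changes were 1.075 times their size without it (median; 0.917 to 1.14). Of the 8, 5 still passed; Antxr1 went from 0.58 to 0.53 (adjusted p = 0.178), Proser3 from 0.54 to 0.62 (0.0962) and Nlrp5-ps from -1.17 to -1.23 (0.0709), the folds moving little while the fit lost a degree of freedom. The 8 genes lie on chromosomes 2 (Napb), 6 (Antxr1), 7 (Hddc3, Proser3, Nlrp5-ps), 14 (Micu2) and X (Gemin8, Cldn34c1). This argues against a single segment, such as one around the targeted gene, as the cause of all 8. Several segments of another strain, linked to the genotype, cannot be told apart from an effect of the KO. In GENCODE M21 order, 4 genes at an unadjusted p under 0.01 (edgeR) lay within 10 tested genes of the 8. Of 10000 random sets, 724 had 4 or more (median 1). The chromosomes of the 8 genes had been seen before that count, and reads shared between copies stay open for Cldn34c1 and Nlrp5-ps.

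The interneuron list was lower in KO hippocampus (median -0.29, 17 of 20 genes negative; camera adjusted p = 2.1e-08, and 0.58 with an estimated correlation). A single hippocampus library is argued against, since the highest median with 1 of the 4 left out was -0.2191, without hippocampus KO replicate 1. Fewer ventral forebrain cells in the KO dissections cannot be told apart from fewer or altered interneurons: the 18 striatal and ventral forebrain markers had a median of -0.1572 (quartiles -0.23 and 0.03, 11 negative), which was 0.01 without hippocampus control replicate 2 and -0.02 without hippocampus KO replicate 1. It was -0.07 on log2(RPKM + 1) and -0.05 on quantile-normalized values, where the interneuron median was -0.25 and -0.26, and the wide spread of the markers, which went both ways, keeps this open. An effect of the KO on interneurons stays among the open explanations.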

How the results depend on the processing

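The Y-linked covariate and the correlations within replicate 1 and within replicate 2 were chosen only after the result was seen. Where no reason is given, the cause was not tested. Srrm4 passed in all 64 fits of the KO contrasts under the alternatives (highest adjusted p 0.0266), with log2 fold changes from -1.85 to -1.25 in cortex, -2.29 to -1.55 in hippocampus and -2.06 to -1.40 over both. The 3 genes of KO cortex became 11 with DESeq2 and 5 with the Y-linked covariate. DESeq2 made more false calls than edgeR in the simulated KO contrasts, so its larger counts do not show more changed genes. The 4 of KO hippocampus became 7 with limma on log2(RPKM + 0.1), 18 with DESeq2, 2 from its 4 libraries alone (fewer samples), and 2 or 1 with RPKM of at least 1 or 5 (fewer genes tested). The 10 over both tissues became 37 with DESeq2, 4 with the mean of cortex and hippocampus per genotype and replicate number (fewer samples), and 22 with the replicate block, the pairing by number. Leaving out a library gave 2 to 3 genes in cortex, 2 to 7 in hippocampus (7 without hippocampus control replicate 1), 5 to 9 over both (5 without cortex control replicate 1 or cortex KO replicate 2), 7440 to 8583 between tissues and 3189 to 5972 between tissues in controls (3189 without cortex control replicate 1). A lone library is assumed there to vary like the other groups. With RPKM of at least 5, 5303 and 3040 genes differed between tissues (fewer genes tested). The Pearson correlation of KO effects was 0.622 there, with Spearman's rho at 0.210. It was 0.261 and 0.329 within replicates 1 and 2, and 0.0672 and 0.0964 with the numbers crossed. With an estimated correlation 0 lists passed in KO cortex, 0 in KO hippocampus, 0 over both tissues and 0 between tissues. The interaction gave 0 genes in 19 of 19 alternatives, DESeq2 included (158 at an unadjusted p under 0.05 in edgeR). The tissue difference of Srrm4 in controls, 0.05 and not past the threshold, ran from -0.003091 (without cortex control replicate 2) to 0.09516 (without cortex control replicate 1). Of 3454 values of named genes under alternatives, 3329 kept direction and side of the threshold, 69 no longer passed with a library left out and 32 under the other alternatives, 23 newly passed and 1 reversed. Most of these 3454 values are of genes named in the tissue contrasts, so their share says little about the KO calls. Of those, Hddc3 and Napb in hippocampus and Proser3 and Nlrp5-ps over both tissues did not pass in most alternatives. En2 in each KO contrast and Hddc3 over both tissues passed in all. Depth sets a floor of 0.0214 to 0.0515 CPM at 3 counts.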

Other observations

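The replicate-number term was examined only after the data were seen; the counts of splits were planned. The libraries numbered 2 differed from those numbered 1 in 1273 genes, 660 higher and 613 lower (edgeR, replicate term). Grin2b, an NMDA receptor subunit gene, was lower (log2 difference -1.02, SE 0.06), as was Igsf9b (-1.06, SE 0.08), while Pisd (0.84, SE 0.05) and Rgs11 (1.16, SE 0.08) were higher, with adjusted p from 0.0019 to 0.0027. Number 1 joins 2 runs and number 2 holds 1 run in every group, per the labels.

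Eif2s3y lay at 4.86 and 25.46 RPKM in cortex control, 3.38 and 0.08 in cortex KO, 5.26 and 26.36 in hippocampus control and 7.46 and 0.08 in hippocampus KO (replicates 1 and 2). Apart from the Y-linked level, the sex of the embryos was not analysed here.

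Of 34 splits of the 8 libraries into 4 and 4 that the model could fit, the real one included, 2 gave as many genes as the genotype split, so chance cannot be excluded by this count for the 10 genes over both tissues. The highest other value, 1668 genes, came from the split by replicate number, which points to a structure of the samples. With the replicate block, over the 8 splits that part all pairs, the real split gave 22 genes and the highest other 1; 8 splits are too few for a share under 0.05. For hippocampus against cortex, 1 of 34 splits gave as many genes, the real one, with 8712 genes against at most 1 in the others. The other splits left the tissue difference in the residual spread, which by itself keeps their counts low. This count therefore cannot decide whether chance plays a part.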
